A study of Oncorhynchus gorbuscha with 76 samples.

How the data were processed

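Gene-level RNA-seq values were analysed for 76 libraries of muscle, head kidney and gonads from ocean, river and spawning pink salmon of both sexes. The deposited files hold expected counts (estimated read counts per gene), not scaled to a common total, with 1 column per library. The authors name Trim Galore 0.6.4, Salmon 1.8.0 and R 4.3.3 without giving their roles or order, and state no genome build, annotation or step from transcripts to genes, so no gene positions are given. The tables list 40756 genes: 32639 are named by a LOC number, 8117 by another symbol, 40754 matched a reference gene table and 703 had no count in any library. Of all values 36.4% were not whole, and counts were rounded to whole numbers for the tests. Stage, sex, tissue and fish number came from the sample labels, and every library was kept in its labelled group. Library names begin with F in fish labelled ocean, O in river and P in spawning; that O stands for river was not checked against another source, and an exchange of ocean and river would change the meaning of every value for them. Among 125 pairs of libraries within groups the smallest chi-square per gene was 12.7, so no 2 libraries of a group were copies of each other.

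Each tissue and sex was fitted apart with edgeR 4.0.16 in R 4.3.3: low counts were removed with filterByExpr by stage, libraries were scaled with TMM, and the 3 stages shared 1 estimate of spread in a quasi-likelihood model. The contrasts were spawning minus ocean, river minus ocean and spawning minus river, with 2-sided tests and a Benjamini-Hochberg adjusted p under 0.05 taken as a call. For muscle and head kidney a joint fit of both sexes tested the sex by stage interaction of spawning minus ocean and the female minus male difference averaged over the stages. Ovary and testis were not compared with each other. Fish numbers of different stages belong to different fish, so no pairing was used. Gene lists were matched by symbol, 27 in muscle, 27 in head kidney and 30 in gonads, and tested with camera (limma 3.58.1) at a preset correlation of 0.01 and with an estimated correlation, adjusted over the lists of a comparison. A second count of called members was adjusted over the list alone. Genes named only by a LOC number are not in the lists, so fbxo32, trim63, cyp19a1a, cyp17a1, cyp11a1, hsd11b2, nr3c1, ighm and pcna, which no symbol matched, are missing from the counts of atrophy, steroidogenesis, lymphocyte, proliferation and other lists. Symbol patterns also took in genes that do other things, such as the kinase genes rps6ka1, rps6ka5, rps6kal and rps6kc1 and the regulator rps19bp1 on the ribosomal protein list, ADAM and ADAMTS proteases on the metalloproteinase list and spag9b on the flagellum list.

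The groups, comparisons, gene lists, key genes and the alternatives not given below as added were fixed before the data were examined, as was the rule for the genes named. That rule takes for spawning minus ocean the 5 largest rises and 5 largest falls among called genes with a symbol, an average log2 CPM of at least 3 and no overlap between the groups, up to 2 called members per list in each direction, and a set of key genes. For the other contrasts it takes 3 genes in each direction, and for the sex tests the 5 genes with the smallest adjusted p. Where all libraries of a group had no count, the fold is a lower bound computed from 3 counts over the group; with 1 to 3 counts in a group the ratio of pooled counts is given with its exact binomial 95% interval. Such bounds and intervals cover counting error only. Picked outside the rule, after their values were seen, were rps6ka5 in female muscle, gapdh, pfkmb and eno3 from ocean to river in muscle of both sexes, the genes given for the library labelled river male 6, acod1 in ocean male 8, the river level of star in female head kidney and flt3. Fish identity was read from genes on in some fish and off in others, picked for equal states in muscle and gonads of the same fish (river fish 6 left out of the picking). This choice was made after the data were seen: genes picked from head kidney and gonads were tried first, at 4 pairs of thresholds, and the muscle library of river male 6 was not looked at in these tries.

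The alternatives were RLE scaling, library size only, no filter, the DESeq2 1.42.0 Wald test, a fit of the 2 compared stages, fish number as a replicate block, limma-voom for the sex tests and leaving out each library in turn. Added after the data were seen were head kidney fits with a renal tubule score, or with that score and a steroidogenesis score, as covariates, the male muscle comparison of ocean and spawning without river male 6, leaving out single libraries in the sex tests and in the head kidney lymphocyte and inflammation lists, and, for the genes called in all 6 combinations of tissue and sex, leaving out single libraries and library size only. The muscle glycolysis tests were run on 4 sets of list members and with 2 smallest numbers of sarcomere genes, all chosen after the data were seen. Other splits of the same libraries into groups of the same sizes were fitted the same way, up to 100 per comparison. The fits were tested on simulated data with the sizes and spreads of these groups and 200 changed genes. Of 2-fold changes 3% were recovered in female muscle, 0% in male muscle, 5% and 4% in female and male head kidney, 17% in ovary and 39% in testis; of 4-fold changes 69%, 5%, 49%, 44%, 74% and 82% were. False calls made up 0% to 4.72% of the calls. Figures were drawn with Python 3.11.15, matplotlib 3.10.9 and numpy 2.4.6 from the same values.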

Results

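Messenger RNA was sequenced from muscle, head kidney and gonads of pink salmon (Oncorhynchus gorbuscha), a salmon that spawns once and then dies. The head kidney of fish makes blood and immune cells and also holds the interrenal cells that produce cortisol. The labels place each fish at 1 of 3 stages, named ocean, river and spawning, and give its sex and number. The 76 libraries fell into 18 groups of stage, sex and tissue, and by their numbers came from 28 fish. Ocean females and river females each gave 4 libraries per tissue. Ocean males gave 5 gonad, 4 head kidney and 4 muscle libraries, and river males gave 5, 4 and 5. Spawning females gave 5 gonad, 4 head kidney and 4 muscle libraries, and spawning males gave 5, 4 and 3. Total counts per library ran from 15784611 to 29286325 in muscle, from 13651505 to 18724203 in head kidney and from 12719694 to 17696550 in gonads. Between 16547 and 27706 genes per library had at least 10 counts. The 10 most abundant genes took 37.4% ± 2.98 (SD, n = 4) of the counts in ocean female muscle and 16.6% ± 6.38 (SD, n = 4) in spawning female muscle. In male muscle they took 39.9% ± 2.80 (SD, n = 4) in the ocean and 15.7% ± 0.617 (SD, n = 3) at spawning. Levels below are CPM after TMM scaling (mean ± SD), and changes are log2 fold changes fitted by edgeR ± SE.

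**Figure D1:**
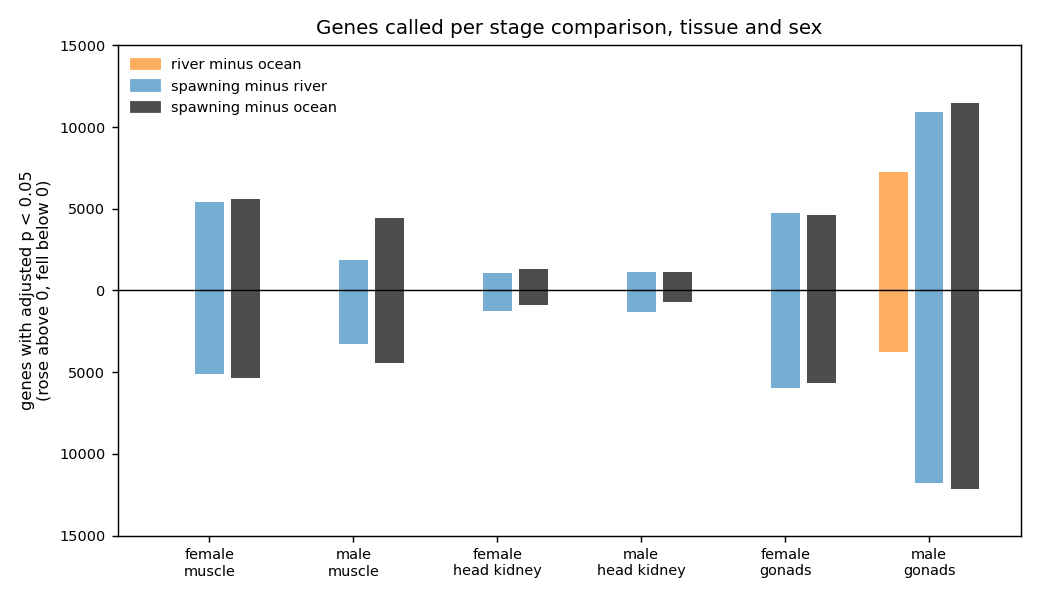
Genes with an adjusted p under 0.05 in the 18 comparisons between stages, by tissue and sex; bars above 0 count genes that rose and bars below 0 genes that fell. Male gonads had the most called genes, with 11462 genes up and 12170 down between ocean and spawning, and 0 genes passed between ocean and river in male head kidney and in female gonads.

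The comparison of spawning with ocean fish spans the whole sampled migration. In female muscle, glycolytic enzymes that were among the most abundant transcripts in the ocean were far lower at spawning. The mean of gapdh, glyceraldehyde-3-phosphate dehydrogenase, went from 28530 ± 8038 CPM (n = 4) to 6.05 ± 3.35 CPM (n = 4), a change of -12.21 ± 1.12 (adjusted p = 6.14e-06). The phosphofructokinase gene pfkmb changed by -12.19 ± 1.10, the enolase eno3 by -11.46 ± 1.02 and the glycogen phosphorylase pygma by -7.15 ± 1.05. A paralog of pfkmb, pfkma, rose by 7.90 ± 0.66, from 3.56 ± 2.19 to 841 ± 444 CPM. The other large rises were fmn2a, an actin nucleator (9.07 ± 0.92), the protein phosphatase ppm1ka (8.69 ± 0.98), the amino acid transporter slc43a1a (8.29 ± 0.95) and avpi1 (7.78 ± 0.71), and the repressor bcl6aa fell by 8.84 ± 0.80.

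Proteasome genes moved the opposite way to glycolytic genes in female muscle. All 12 tested proteasome subunits rose (12 adjusted over the list alone), with the ATPase psmc6 at 1.90 ± 0.28. Of 18 autophagy and lysosomal protease genes, 10 rose and 2 fell (12 and 2 adjusted over the list alone), among them the autophagy initiator atg13 (2.22 ± 0.25) and the lysosomal regulator tfeb (2.12 ± 0.29), although camera did not call this list (adjusted p = 0.0722). Of 7 genes of cell-cycle arrest and p53 targets, 4 rose (4 adjusted over the list alone), with sesn1 at 4.53 ± 0.46 and the CDK inhibitor cdkn1ba at 4.38 ± 0.38. Of 14 glycolysis genes, 10 fell and 2 rose (10 and 3 adjusted over the list alone). Of 32 genes on the ribosomal protein list, 25 fell and 1 rose (26 and 1 adjusted over the list alone), with rpl34 at -2.59 ± 0.29. The riser was rpl7l1, and 1 faller, rps6ka5, is a kinase (rpl7l1 had an adjusted p of 0.0994 with fish number as a replicate block). Collagen and matrix genes fell in 14 of 17 cases (14 adjusted over the list alone), with col1a2, a chain of type I collagen, at -3.08 ± 0.38. Markers of other tissues fell in part too: 3 of 8 epithelium and skin genes (3 adjusted over the list alone; preset adjusted p = 0.550), with ppl at -5.27 ± 1.14 and agr2 at -3.99 ± 1.397 (adjusted p = 0.0284, 0.0573 to 0.654 without ocean female 7 or spawning female 3, 4 or 5, and 0.790 with fish number as a replicate block). Of 9 endothelial genes 4 fell and 1 rose (4 and 1 adjusted over the list alone; preset adjusted p = 0.366), with kdr at -1.33 ± 0.23 and tek at -0.95 ± 0.21 (0.0749 and 0.580 with library-size scaling, and 0.107 for tek with the replicate block) and plvapb at 2.18 ± 0.51. Of 7 erythroid genes 3 fell (3 adjusted over the list alone; preset adjusted p = 0.587), with hemgn at -1.51 ± 0.39 (0.0671 with library-size scaling and 0.0856 with the replicate block). In the list of fatty acid oxidation and lipid handling 11 of 16 genes fell and 2 rose (12 and 2 adjusted over the list alone): angptl4 changed by -6.18 ± 0.62 and pdk4, which restrains pyruvate oxidation, by 2.28 ± 0.53. Of 3 adipocyte genes 2 fell with them (2 adjusted over the list alone; preset adjusted p = 0.467), adipoqa by 2.59 and plin1 by 1.51 (adjusted p = 0.115 for plin1 with library-size scaling and 0.0660 with the replicate block). Of 15 genes on the list of matrix metalloproteinases and inhibitors, 9 fell and 1 rose (9 and 1 adjusted over the list alone). The riser adam9 and the fallers adam17b, adam19a, adamts1, adamts10, adamts12 and adamts15a are ADAM or ADAMTS proteases, which are not matrix metalloproteinases. The other fallers were mmp15a, mmp19 and the inhibitor timp2a.

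At a preset correlation camera called 7 of the 27 lists in this comparison: proteasome (adjusted p = 4.88e-05), arrest and p53 targets (0.00280), glycolysis (0.00157), the ribosomal protein list (6.05e-09), collagen (2.77e-05), lipid handling (0.00363) and the metalloproteinase list (0.0152). None was called with an estimated correlation, where the adjusted p was 0.446 for arrest and p53 targets and 0.4935 for each of the other 6. Growth and contraction genes went both ways: the growth factor igf1 was low throughout (0.670 ± 0.511 CPM in the ocean) and 66.0-fold lower at spawning (95% counting interval 11.3 to 2658), where the 4 libraries held 1 count. Its binding proteins igfbp1a and igfbp3 changed by 5.55 ± 0.64 and -2.26 ± 0.35, and the myogenic factor myf6 by 4.21 ± 0.45. The myostatin gene mstnb stood at -0.17 ± 0.67 (adjusted p = 0.854). Of 10 sarcomere genes 3 rose and 3 fell (3 and 3 adjusted over the list alone; preset adjusted p = 0.923), with neb at 4.80 ± 0.67, the actin actc1a at 3.63 ± 0.63, fast troponin T, tnnt3a, at -3.13 ± 0.66 and myom1b at -1.54 ± 0.34. The muscle calpain capn3b changed by -5.15 ± 0.63. The cortisol-responsive genes fkbp5 and klf9 rose by 3.12 ± 0.70 and 3.61 ± 0.71. In all, 5591 genes rose and 5359 fell of 21695 tested (5422 in total with fish number as a replicate block). With library size as the only scaling the median of all tested genes moved from -0.01 to 0.76, and 9461 genes rose and 2635 fell.

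The river stage separates the migration into an ocean-to-river and a river-to-spawning step. In female muscle the later step called more genes: from river to spawning 5396 genes rose and 5091 fell, with fmn2a 3272-fold (95% counting interval 1119 to 15868) and slc43a1a 2466-fold (442 to 97440) higher than in the river, where they had 3 counts and 1 in all, ppm1ka at 9.33 ± 1.00, pfkmb at -9.52 ± 1.00, gapdh at -9.13 ± 1.01 and bcl6aa at -8.66 ± 0.80. In that step 11 of 12 proteasome genes rose and 13 of 17 collagen genes fell (12 and 13 adjusted over the list alone; preset adjusted p = 3.17e-04 and 4.05e-05, adjusted p = 0.777 and 0.775 with an estimated correlation). Library-size scaling moved the median of all genes by 0.21 there. From ocean to river 3 genes rose and 6 fell with edgeR, with 2208 at an unadjusted p under 0.05, about 3.5e+02 called with DESeq2, 107 in a fit of these 2 stages and 14 without a filter. Of 14 glycolysis genes 0 were called (0 up and 6 down adjusted over the list alone; preset adjusted p = 3.69e-09, adjusted p = 0.270 with an estimated correlation). Of these, gapdh stood at -3.08 ± 0.76 (adjusted p = 0.171), with 3380 ± 3194 CPM in the river, pfkmb at -2.67 ± 0.73 (0.220) and eno3 at -4.04 ± 0.74 (0.0890). A called gene with a symbol, si:dkeyp-69b9.3, stood at 1.34 ± 0.20 (adjusted p = 0.0347), whose adjusted p was 0.117 to 0.158 without any 1 of ocean females 2, 4, 5 and 7 and river females 1, 7 and 9. No gene was called without any 1 of ocean females 2, 5 and 7 and river females 1, 7 and 9, 3 were without ocean female 4 and 45 without river female 8. Library-size scaling gave 488 up and 24 down around a median of 0.55.

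In male muscle large falls between ocean (n = 4) and spawning (n = 3) again included glycolytic enzymes, and proteasome genes rose. The change of gapdh was -11.74 ± 2.11 (adjusted p = 0.00281), from 40550 ± 13300 to 11.8 ± 2.83 CPM, and those of pfkmb and eno3 were -12.94 ± 2.12 and -12.65 ± 2.22. The creatine synthesis gene gatm changed by -10.50 ± 1.52, and ntmt2 was at least 505-fold lower at spawning, where its 3 libraries held no count (the bound takes 3 counts over the group). Rises included fmn2a (1155-fold, 95% counting interval 319 to 9540, against 2 counts in the ocean), pfkma (8.85 ± 2.54), the zinc transporter slc39a14 (8.83 ± 2.15) and tspan36 (7.58 ± 2.19). The gene avpi1 rose by 8.01 ± 2.44 but had an adjusted p of 0.0565, 0.0581 and 0.0505 without ocean male 1, 3 or 9. All 12 tested proteasome genes rose (12 adjusted over the list alone), such as psmc6 (3.23 ± 0.72) and psma4 (2.09 ± 0.46). Of 14 glycolysis genes 7 fell and 2 rose (7 and 2 adjusted over the list alone). Of 33 genes on the ribosomal protein list 24 fell and 1 rose (25 and 1 adjusted over the list alone), with rps20 at -2.29 ± 0.48. The riser was rpl7l1, and 1 faller, rps6ka5, is a kinase. Of 17 lipid genes 12 fell and 3 rose (12 and 3 adjusted over the list alone), and of 3 adipocyte genes 1 fell, adipoqa by 3.68 (1 adjusted over the list alone; preset adjusted p = 0.658). Of 25 oxidative phosphorylation genes 14 fell and 1 rose (14 and 1 adjusted over the list alone; preset adjusted p = 0.00539, but 0.388 with library-size scaling, and adjusted p = 0.740 with an estimated correlation). Of 6 epithelium and skin genes 1 fell (0 adjusted over the list alone; preset adjusted p = 0.945), of 9 endothelial genes 1 rose (1 adjusted over the list alone; preset adjusted p = 0.978), and none of 8 erythroid genes was called (0 adjusted over the list alone). The other 4 called lists described had preset adjusted p values of 5.47e-06 for proteasome, 0.0107 for glycolysis, 1.06e-04 for the ribosomal protein list and 0.00539 for lipid handling; for each of these 4, adjusted p = 0.740 with an estimated correlation.

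Sarcomere genes went both ways in male muscle: of 10, 4 fell and 2 rose (4 and 3 adjusted over the list alone; preset adjusted p = 0.658), with the fast troponin tnnt3a at -3.82 ± 0.63, the fast myosin light chain myl1 at -4.9986 ± 0.92 and neb at 5.16 ± 1.28. The calpain capn3b changed by -7.17 ± 1.14. Of the growth genes, mstnb changed by -5.61 ± 1.00, igfbp1a by 6.95 ± 1.395 and myf6 by 4.85 ± 0.99. The selective autophagy receptor sqstm1 rose by 2.16 ± 0.54 and cdkn1ba by 5.27 ± 1.20. The change of klf9 was 5.76 ± 1.43 and that of fkbp5 4.36 ± 1.30 (adjusted p = 0.0197, and 0.0516 without ocean male 1). In all, 4447 genes rose and 4419 fell of 22042 tested, with 5766 called in total without spawning male 8 and 5464 without spawning male 9. Library-size scaling moved the median of all genes from 0.03 to 1.18 and gave 10894 genes up and 1499 down.

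From river (n = 5) to spawning (n = 3), 1842 genes rose and 3285 fell in male muscle (3061 in total in a fit of these 2 stages): igfbp1a changed by 5.94 ± 1.21, btbd11b by 3.77 ± 0.67, gatm by -9.33 ± 1.46, the scaffold gene homer1b by -7.61 ± 1.12 and the sulfate transporter slc13a4 by -7.33 ± 1.20. The rise of fmn2a (4.31 ± 1.45, adjusted p = 0.0482) is lost with DESeq2 (0.110), library-size scaling (0.0625) and a fit of these 2 stages (0.102), and without any 1 of river males 2 to 5 and spawning males 7 to 9 (0.0521 to 0.127). From ocean to river 8 genes rose and 24 fell with edgeR (3059 at an unadjusted p under 0.05, 747 with DESeq2, 15 in a fit of these 2 stages). In this step 0 of 14 glycolysis genes were called (1 up and 7 down adjusted over the list alone; preset adjusted p = 5.44e-06, adjusted p = 0.239 with an estimated correlation). Of these, gapdh stood at -3.65 ± 1.19 (adjusted p = 0.227), pfkmb at -2.89 ± 1.11 (0.285) and eno3 at -4.75 ± 1.27 (0.169). Among the called genes was cited2, a transcriptional co-regulator, at -2.27 ± 0.37 (adjusted p = 0.0454, 0.0612 in a fit of these 2 stages, and 0.0655 to 0.141 without any 1 of ocean males 1, 3, 8 and 9 and river males 2 to 5). So was tecrb at -1.42 ± 0.25 (0.0499), lost without the same libraries (0.0809 to 0.154), with library-size scaling (0.168), in a fit of these 2 stages (0.0712) and without a filter (0.0803). The library labelled river male 6 muscle stood apart from the other 4 river males and close to the spawning libraries. Its gapdh level was 3.86 CPM against 786 to 7316 in the other 4, eno3 1.06 against 164 to 2284, pfkma 1495 against 0.790 to 3.53, psmc6 1062 against 125 to 230 and fkbp5 239 against 6.92 to 12.7. Without it 219 genes were called between ocean and river, 11077 between river and spawning and 10948 between ocean and spawning, an alternative added after the data were seen; gapdh, eno3, pfkmb, pfkma, psmc6 and fkbp5 stayed called in the last of these. Other single libraries also moved the river counts. Between ocean and river, 0 genes were called without ocean male 3 or 9, 3 without ocean male 1, 2 without ocean male 8, 1 without river male 2, 3 or 4 and 15 without river male 5. From river to spawning, 2995, 3221, 2879 and 3005 were called without river males 2, 3, 4 and 5, and 1444 and 1877 without spawning males 8 and 9. With library-size scaling 6260 genes rose and 64 fell from ocean to river around a median of 0.94, and 1584 rose and 1814 fell from river to spawning around a median of 0.27.

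The muscle changes from ocean to spawning overlapped between the sexes: of 21123 genes tested in both, 3505 rose in both, 3129 fell in both and 24 went opposite ways, where independent calls would give 1122 and 1069 shared rises and falls. A direct test of the sex difference in this change, with both sexes in 1 fit, called 12 genes, 8 with the higher change in females and 4 in males (295 with DESeq2, 5 with limma-voom and 5 with library-size scaling, 1 up and 4 down around a median of -0.34). That count ranged from 1 to 143 when single libraries were left out: 1 without ocean female 2 or 4, ocean male 3 or spawning male 8, 3 without ocean female 7, spawning female 2 or spawning male 7, 5 without ocean female 5 and 7 without ocean male 1. It was 25 without spawning female 3, 29 without spawning female 4 and 143 without spawning male 9. Averaged over the stages, 70 genes were higher and 79 lower in female than in male muscle (620 in total with DESeq2 and 45 with limma-voom). The cell-cycle gene cks2 was lower in females by -1.93 ± 0.27 (adjusted p = 7.74e-04), and the progesterone receptor pgr (3.84 ± 0.66), rasgrp3 (1.30 ± 0.20), arl13a (1.42 ± 0.26) and the muscle kinase alpk3a (0.94 ± 0.17) were higher. The number of sex differences was 273 without river male 6 and 398 without spawning male 9. It was between 53 and 92 without any 1 of ocean females 4, 5 and 7, ocean males 3 and 9, river females 1, 7, 8 and 9, spawning female 2 and spawning male 7. Library-size scaling gave 158 higher and 39 lower around a median of 0.18.

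**Figure D2:**
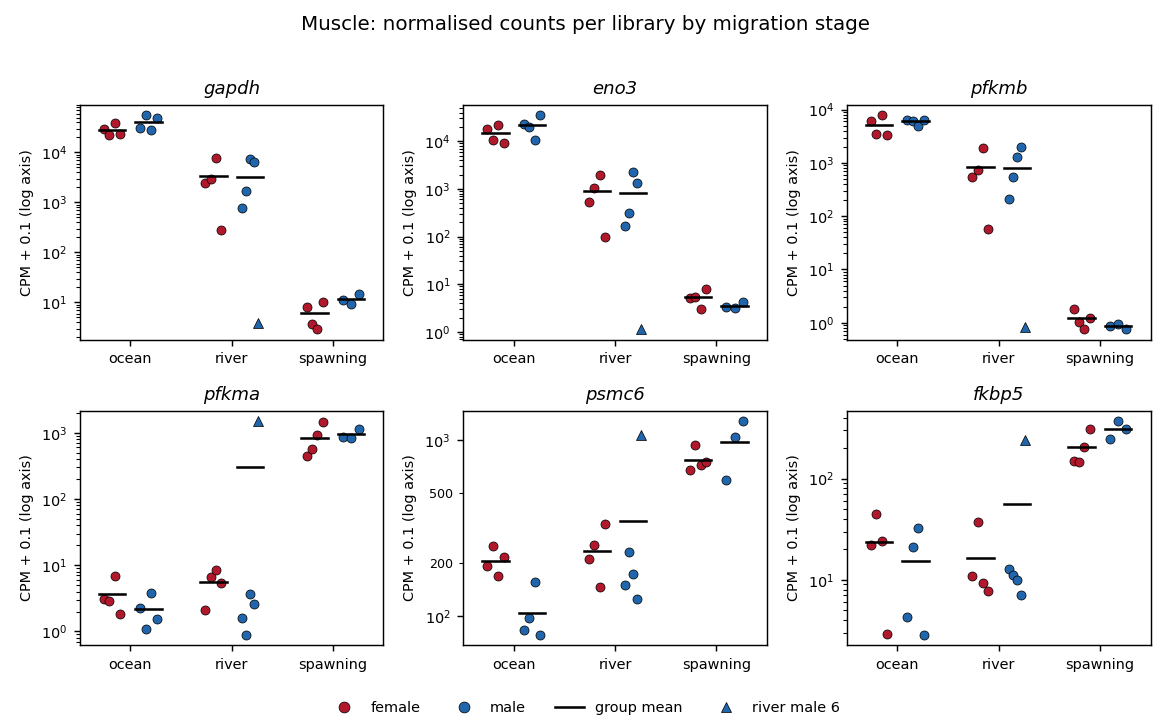
Levels of 6 genes in each muscle library (CPM + 0.1, log axis) at the 3 stages, females in red and males in blue, with a black bar at each group mean and the library labelled river male 6 as a triangle. In that library gapdh was at 3.86 CPM and pfkma at 1495 CPM, on the side of the spawning libraries.

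In female head kidney, lymphocyte genes fell and inflammatory genes rose between ocean (n = 4) and spawning (n = 4). Of 14 lymphocyte genes 9 fell and none of the others passed (11 down and 1 up adjusted over the list alone; preset adjusted p = 2.49e-10, 0.0229 with an estimated correlation). The T-cell co-receptor cd8a went from 11.99 ± 5.83 to 0.575 ± 0.268 CPM, a change of -4.36 ± 0.61 (adjusted p = 0.00307), the T-cell kinase lck changed by -2.21 ± 0.32 and the recombinase rag1, which assembles antigen receptor genes, by -4.31 ± 0.77. Granzyme gzma changed by -2.85 ± 0.43 and the lymphocyte signalling adaptor sh2d1ab by -2.74 ± 0.29. Of 8 inflammation and acute phase genes 3 rose (4 adjusted over the list alone; preset adjusted p = 6.11e-05, 0.0229 with an estimated correlation), and acod1, the itaconate-producing enzyme of activated macrophages, rose by 6.46 ± 0.68, from 0.409 ± 0.111 to 36.7 ± 31.2 CPM. Other large rises were the peptidoglycan recognition gene pglyrp5 (4.06 ± 0.26), si:ch1073-126c3.2 (4.47 ± 0.79), the oxidase ero1a (3.65 ± 0.69) and transferrin, tfa (3.47 ± 0.52), and large falls were those of the organic anion transporter slc22a6l (-8.69 ± 1.69) and mctp1a (-2.64 ± 0.48).

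Of 19 autophagy genes 1 rose (8 adjusted over the list alone; preset adjusted p = 7.69e-04, 0.0296 with an estimated correlation). The glycolysis, glucocorticoid response, antigen presentation, ribosomal protein, interferon and complement lists were called with the preset correlation and not with an estimated one. Glycolysis genes rose in 5 of 13 cases (5 adjusted over the list alone), such as aldoaa (1.35 ± 0.19) and pkma (0.99 ± 0.19), with a preset adjusted p of 0.0160 and adjusted p = 0.414 with an estimated correlation. Of 6 glucocorticoid response genes 2 rose, fkbp5 by 2.42 ± 0.26 and klf9 by 1.89 ± 0.28 (2 up and 1 down adjusted over the list alone; preset adjusted p = 0.0101, 0.212 with an estimated correlation). Of 5 antigen presentation genes 1 fell, cd74b by 1.75 ± 0.35 (4 adjusted over the list alone; preset adjusted p = 0.00580, 0.410 with an estimated correlation). Of 33 genes on the ribosomal protein list, 4 of them kinase or kinase-like genes that were not called, 3 fell (17 adjusted over the list alone; preset adjusted p = 1.14e-05, 0.443 with an estimated correlation). Of 10 interferon response genes 1 rose (5 adjusted over the list alone; preset adjusted p = 0.00382, 0.443 with an estimated correlation), as did 1 of 11 complement and macrophage genes (4 adjusted over the list alone; preset adjusted p = 0.0262, 0.414 with an estimated correlation). None of 25 cell proliferation genes was called (0 adjusted over the list alone), and mki67 stood at -0.13 ± 0.28 (adjusted p = 0.833). In all, 1306 genes rose and 861 fell of 27374 tested; the total was 1174, 1158, 1167 and 887 without ocean females 2, 4, 5 and 7 and 1402 without spawning female 1. It was 4339 with DESeq2, 3901 with tubule and steroidogenesis scores in the model and 59 with fish number as a replicate block. Library-size scaling moved the median of all genes from -0.06 to -0.25 and gave 755 genes up and 1418 down.

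The share of renal tubule tissue differed among the head kidney libraries. A score of the renal tubule list, the mean log2 CPM of its members, ran from -1.60 to 5.93 over the 24 libraries. It was above 0 in 4 of 4 ocean females, 1 of 4 river females, 2 of 4 spawning females, 2 of 4 ocean males, 2 of 4 river males and 1 of 4 spawning males. In females 1 of 13 tubule genes fell from ocean to spawning (1 adjusted over the list alone; preset adjusted p = 0.0254, 0.120 with library-size scaling, adjusted p = 0.688 with an estimated correlation). The steroid transport gene star, a marker of interrenal cells, also varied, with 0.170 ± 0.134 CPM in ocean, 917 ± 1608 in river and 1095 ± 1777 in spawning females. The steroidogenesis list had 0 called genes of 11 (4 adjusted over the list alone; preset adjusted p = 0.336). The mean of the lymphocyte list, by contrast, was 3.27 to 4.00 in ocean, 3.27 to 4.29 in river and 1.51 to 2.38 in spawning libraries of both sexes. In 15 genes that were on in some fish and off in others (above 2 and under 0.2 CPM), 22 of 24 head kidney libraries had the same state as the gonad library of the same number in every gene. The head kidney library labelled ocean female 7 equalled the gonad library of ocean female 2 in 14 of 14 genes and its own in 10 of 14. Ocean female 2 has a head kidney library of its own, so this label and the number of 4 ocean fish in female head kidney are in doubt. Without that library 8 of 14 lymphocyte genes fell and 2 of 8 inflammation genes rose from ocean to spawning (preset adjusted p = 1.63e-10 and 8.04e-05). The one labelled ocean male 1 equalled the gonad library of ocean male 3 in 14 of 14 and its own in 12 of 15.

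From river to spawning, female head kidney again lost lymphocyte transcripts: 10 of 14 genes fell (12 adjusted over the list alone; preset adjusted p = 3.50e-20, 0.00351 with an estimated correlation), with cd8a at -4.62 ± 0.62 and sh2d1ab at -3.65 ± 0.30. The rise of acod1 was 5.81 ± 0.66, that of wu:fj16a03 5.40 ± 1.04 (adjusted p = 0.0684 with both scores in the model) and that of si:ch211-39i22.1 4.86 ± 0.82. The gene si:dkey-85k7.10 changed by -3.86 ± 0.77, and 26 of 33 genes on the ribosomal protein list fell, none of them among its 4 kinase or kinase-like genes (27 adjusted over the list alone; preset adjusted p = 8.08e-27, 0.105 with an estimated correlation). In this step 1067 genes rose and 1248 fell, 1341 in total without river female 7, 3943 with DESeq2, 4088 with a tubule score in the model and 907 in a fit of these 2 stages. From ocean to river 7 genes rose and 25 fell with edgeR (4098 at an unadjusted p under 0.05, 1536 with DESeq2, 1283 with a tubule score, 5 with tubule and steroidogenesis scores and 4 without a filter; 2 and 27 with library-size scaling around a median of -0.19). The choline transporter-like gene slc44a5b changed by -1.90 ± 0.23 (adjusted p = 0.0233, 0.0505 with tubule and steroidogenesis scores in the model, and 0.0537 to 0.143 without any 1 of ocean females 2, 4, 5 and 7 and river females 7, 8 and 9). The calls of ucp2 (1.17 ± 0.18), tmsb4x (1.07 ± 0.17), aplp2 (-2.19 ± 0.32) and gk5 (-1.95 ± 0.29), with adjusted p of 0.0455 to 0.0477, are lost in a fit of these 2 stages, without a filter, with both scores (0.0505 to 0.0646) and without any 1 of the same 7 libraries (0.0748 to 0.221), that of tmsb4x also with library-size scaling (0.0661) and without river female 1 (0.0537). No gene was called without any 1 of ocean females 2, 4 and 7 and river females 8 and 9, 5 were without ocean female 5, 4 without river female 7 and 83 without river female 1. None of 13 tubule genes passed over all genes (2 fell adjusted over the list alone; adjusted p = 0.47 with an estimated correlation).

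Male head kidney also had fewer lymphocyte transcripts at spawning (n = 4) than in the ocean (n = 4). Of 14 lymphocyte genes 8 fell (9 down and 1 up adjusted over the list alone; preset adjusted p = 1.21e-06, 0.101 with an estimated correlation), with gzma at -3.21 ± 0.49 and the T-cell factor bcl11ba at -3.42 ± 0.52. Fewer fell without some libraries, 4 without ocean male 6 or spawning male 7 or 10 and 5 without ocean male 9 or spawning male 6 or 9. Of 9 inflammation genes (median 0.19) 3 rose (3 adjusted over the list alone, preset adjusted p = 6.69e-05, 0.0378 with an estimated correlation). The gene nfkbiab, an NF-kappa-B inhibitor, changed by 2.79 ± 0.24 and the cytokine il10 was at least 77.6-fold higher than in ocean males, whose 4 libraries held no count. Red cell genes fell too, 5 of 10 on the erythroid list (6 adjusted over the list alone; preset adjusted p = 1.68e-06, 0.101 with an estimated correlation), including rhag (-2.81 ± 0.41) and the mitochondrial iron importer slc25a37 (-3.11 ± 0.54). Of 5 antigen presentation genes 3 fell (5 adjusted over the list alone; preset adjusted p = 6.69e-05, 0.101 with an estimated correlation), with the peptide transporter tap1 at -0.81 ± 0.14 and tapbp.1 at -1.26 ± 0.21. Of 19 collagen and matrix genes 4 fell (11 down and 2 up adjusted over the list alone; preset adjusted p = 6.69e-05, 0.112 with an estimated correlation), with serpinh1a at -2.0032 ± 0.27. Of 11 complement and macrophage genes 2 rose, c7b by 2.56 ± 0.35 and marco by 1.67 ± 0.27 (4 adjusted over the list alone; preset adjusted p = 0.00137, 0.112 with an estimated correlation). Single genes with large rises were rassf1 (3.55 ± 0.57), pglyrp5 (3.40 ± 0.57), znrf1 (3.28 ± 0.29), klf9 (3.20 ± 0.62) and angptl4 (2.94 ± 0.23). Large falls were those of si:dkey-93h22.7 (-4.54 ± 0.64), klf1 (-5.12 ± 1.08, adjusted p = 0.0611 without spawning male 10), nmt1b (-5.05 ± 1.13, 0.0669 to 0.0738 without spawning male 7, 9 or 10) and dnah10 (-6.37 ± 1.44, 0.0509 to 0.0710 without ocean male 1 or 6 or spawning male 6, 7 or 10). The fall of sycp1 (-6.76 ± 1.54) is lost without ocean male 6 or any 1 spawning male (0.0527 to 0.0792) and in a fit of these 2 stages (0.0506).

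None of 25 cell proliferation genes was called in male head kidney (0 adjusted over the list alone), with mki67 at 0.13 ± 0.26 (adjusted p = 0.817). The renal tubule list had 0 called genes of 11 (0 adjusted over the list alone; preset adjusted p = 0.0839). In ocean male 8, acod1 stood at 137 CPM, against 0.334 to 0.908 in the other 3 ocean males. In all, 1121 genes rose and 698 fell of 26897 tested; 3462 were called without ocean male 8, 999, 942 and 1201 without ocean males 1, 6 and 9, and 1132, 1063, 1167 and 991 without spawning males 6, 7, 9 and 10. DESeq2 called 3671, and a fit with fish number as a replicate block 0. Library-size scaling moved the median of all genes from -0.10 to -0.24 and gave 956 genes up and 987 down.

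From river to spawning 1157 genes rose and 1322 fell in male head kidney. Rises included si:ch1073-126c3.2 (8.47 ± 1.95, adjusted p = 0.0229) and acod1 (6.86 ± 1.89, 0.0447). Falls included dnah10 (-6.32 ± 1.44, 0.0220) and sycp1 (-5.15 ± 1.45, 0.0484). None of the 4 holds throughout, and carry-over of sycp1 from testis was not tested at any stage. Without any 1 of the 8 river and spawning males acod1 had an adjusted p of 0.0681 to 0.108 and sycp1 of 0.0664 to 0.122, and without a filter 0.0531 and 0.0589. The call of si:ch1073-126c3.2 is lost without river male 2, 3 or 6 (0.0605 to 0.0694), and that of dnah10 without river male 2 or spawning male 6, 7 or 10 (0.0535 to 0.0666). The matrix proteoglycan lum changed by -4.10 ± 0.83, and 8 of 19 collagen and matrix genes fell and 1 rose (12 and 1 adjusted over the list alone; preset adjusted p = 4.60e-06, 0.0993 with an estimated correlation). Transferrin, tfa, rose by 4.64 ± 0.97 (adjusted p = 0.0153, and 0.0510 without river male 2), and 8 of 14 lymphocyte genes fell (10 adjusted over the list alone; preset adjusted p = 2.77e-09, adjusted p = 0.0993 with an estimated correlation). The total was 1113, 1537 and 1487 without river males 2, 3 and 6 and 1123, 1120 and 1300 without spawning males 6, 7 and 10, and 4743 with DESeq2. From ocean to river edgeR called 0 genes, with 2669 at an unadjusted p under 0.05, 170 with DESeq2 and 1 without river male 6. Between the sexes, 626 of 26329 genes tested in both rose from ocean to spawning in both and 227 fell in both, against 55.2 and 20.2 for independent calls, and 0 went opposite ways. The test of a sex difference in this change called 0 genes with edgeR and 0 with limma-voom, against 96 with DESeq2 and 1314 at an unadjusted p under 0.05. The smallest adjusted p belonged to the lipid regulator srebf1 (2.64 ± 0.51, adjusted p = 0.278). The erythroid list differed in that test (0 of 10 called, 4 adjusted over the list alone with the higher change in females; preset adjusted p = 3.73e-11, adjusted p = 0.00168 with an estimated correlation). Averaged over the stages, 5 genes were higher and 10 lower in female head kidney, with the erythrocyte carbonic anhydrase cahz at -3.25 ± 0.45 (adjusted p = 0.00446, and 0.0836 with limma-voom, which called 0; DESeq2 called 372 and RLE scaling gave 5 and 17). Their number was 48, 26 and 29 without ocean males 1 and 8 and river male 5, and 6, 8 and 26 without spawning females 1, 2 and 5.

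**Figure D3:**
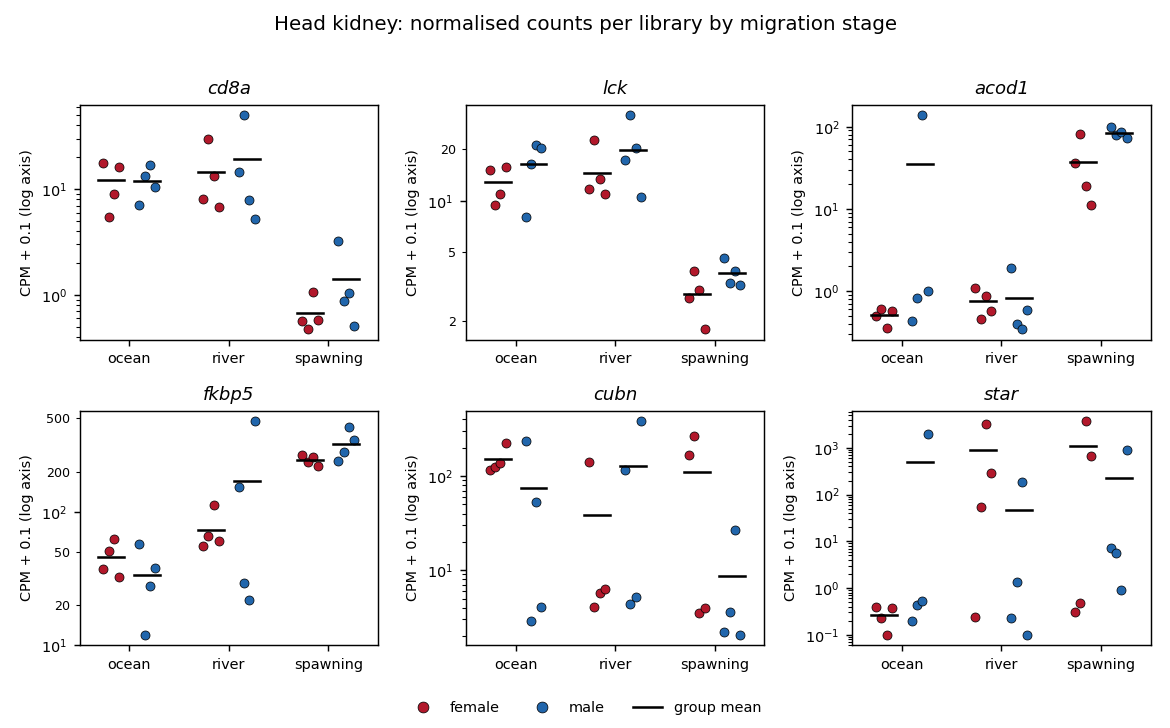
Levels of 6 genes in each head kidney library (CPM + 0.1, log axis) at the 3 stages, females in red and males in blue, with a black bar at each group mean. The T-cell gene cd8a is low in the spawning libraries, whereas cubn (renal tubule) and star (interrenal) spread widely within stages; star was at 3321 CPM in river female 8.

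In the ovary, steroid synthesis and cortisol-responsive genes rose between ocean (n = 4) and spawning (n = 5), and matrix and cell division genes fell. The cholesterol transport gene star, which starts steroid synthesis, went from 37.4 ± 18.2 to 958 ± 295 CPM, a change of 4.68 ± 0.41 (adjusted p = 6.55e-06), and hsd3b1 rose by 5.40 ± 0.45. Of 11 steroidogenesis genes 7 rose. With 8 up and 0 down adjusted over the list alone, the list had a preset adjusted p of 2.98e-06, and adjusted p = 0.0225 with an estimated correlation. The gonadotropin receptors fshr and lhcgr rose by 3.96 ± 0.33 and 2.01 ± 0.32. Of 6 glucocorticoid response genes 3 rose (3 up and 0 down adjusted over the list alone; preset adjusted p = 1.33e-04, adjusted p = 0.0246 with an estimated correlation). Of these, fkbp5 went from 40.1 ± 15.2 to 1238 ± 142 CPM (4.95 ± 0.30) and klf9 changed by 3.26 ± 0.37. Of 26 cell proliferation genes 19 fell and 1 rose, with mki67 at -4.63 ± 0.35 and the replication helicase subunit mcm4 at -3.17 ± 0.16. With 1 up and 20 down adjusted over the list alone, the list had a preset adjusted p of 9.23e-14, and adjusted p = 0.142 with an estimated correlation. Of 23 collagen and matrix genes 17 fell and 1 rose, and the large falls included the matrix genes lum (-5.41 ± 0.34), tnca (-5.38 ± 1.16, adjusted p = 0.131 with fish number as a replicate block) and ogna (-5.17 ± 0.50), the smooth muscle actin acta2 (-5.36 ± 0.71) and the Wnt inhibitor frzb (-5.35 ± 0.73). With 1 up and 18 down adjusted over the list alone, the list had a preset adjusted p of 1.85e-13, and adjusted p = 0.123 with an estimated correlation. Large rises included coagulation factor f5 (6.89 ± 0.51), rapgef4a (6.41 ± 0.29), adam22 (6.33 ± 0.44), the chloride channel cftr (5.99 ± 0.43) and si:dkey-177p2.18 (5.99 ± 0.61).

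On the ribosomal protein list 27 of 33 genes fell in the ovary and 1 rose (1 up and 28 down adjusted over the list alone; preset adjusted p = 2.19e-22, adjusted p = 0.123 with an estimated correlation). The riser, rps6kc1, is a kinase-like gene (0.195 with fish number as a replicate block) and rpl22l1 changed by -2.14 ± 0.17. Of 12 genes on the list of Sertoli and Leydig cells, the somatic cells of the testis, 9 rose (9 up and 0 down adjusted over the list alone; preset adjusted p = 2.33e-06, adjusted p = 0.123 with an estimated correlation). The list holds genes that ovarian follicle cells also express, such as amh (2.57 ± 0.48). Of 19 autophagy genes 13 rose and 1 fell, with atg2a at 1.56 ± 0.21. With 14 up and 1 down adjusted over the list alone, the list had a preset adjusted p of 2.21e-05, and adjusted p = 0.186 with an estimated correlation. All 5 antigen presentation genes fell (0 up and 5 down adjusted over the list alone; preset adjusted p = 4.37e-04, adjusted p = 0.142 with an estimated correlation). So did 6 of 9 lymphocyte genes (1 up and 6 down adjusted over the list alone; preset adjusted p = 0.0171, adjusted p = 0.337 with an estimated correlation). Of these, lck was at least 23.2-fold lower at spawning (adjusted p = 0.0789 with the replicate block). Of 10 erythroid genes 5 fell too (0 up and 5 down adjusted over the list alone; preset adjusted p = 0.215, adjusted p = 0.685 with an estimated correlation), with hemgn at -4.14 ± 0.85 and alas2 at -3.25 ± 0.85 (adjusted p = 0.00979, 0.0523 without ocean female 4 and 0.0619 with the replicate block). Of 10 endothelial genes 6 fell and 1 rose, with a preset adjusted p of 0.0521 under library-size scaling. With 1 up and 7 down adjusted over the list alone, the list had a preset adjusted p of 0.0343, and adjusted p = 0.540 with an estimated correlation. The yolk protein gene vtg3 stood at 0.98 ± 1.07 (adjusted p = 0.512). In all, 4608 genes rose and 5678 fell of 28339 tested (5528 in total with fish number as a replicate block); library-size scaling moved the median of all genes from -0.02 to 0.16 and gave 6148 up and 4238 down.

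The ovary changed between river (n = 4) and spawning: 4772 genes rose and 5962 fell, with the potassium channel kcnk3a at 9.17 ± 1.07, nitric oxide synthase nos1 at 7.57 ± 0.96, slc4a8 at 6.97 ± 1.47, rbp7b at -5.17 ± 0.55, fabp2 at -5.07 ± 0.51 and lum at -4.96 ± 0.33. Steroidogenesis genes rose in 8 of 11 cases (8 up and 0 down adjusted over the list alone; preset adjusted p = 1.00e-04, adjusted p = 0.0217 with an estimated correlation). Glucocorticoid response genes rose in 4 of 6 cases (4 up and 0 down adjusted over the list alone; preset adjusted p = 1.00e-04, adjusted p = 0.0217 with an estimated correlation). Of 26 cell proliferation genes 17 fell and 1 rose. With 1 up and 17 down adjusted over the list alone, the list had a preset adjusted p of 7.14e-09, and adjusted p = 0.292 with an estimated correlation. Library-size scaling gave 6201 up and 4422 down around a median of 0.17. Between ocean and river edgeR called 0 genes in the ovary, with 2338 at an unadjusted p under 0.05 and 149 with DESeq2.

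In the testis, transcripts of germ cells fell between ocean (n = 5) and spawning (n = 5), and transcripts of somatic cells rose. Of 28 germ cell and meiosis genes 27 fell and 1 rose. With 1 up and 27 down adjusted over the list alone, the list had a preset adjusted p of 9.26e-35, and adjusted p = 0.00653 with an estimated correlation. The synaptonemal complex gene sycp1 went from 6899 ± 2738 to 0.0768 ± 0.0829 CPM (-16.33 ± 0.77, adjusted p = 3.39e-11), and smc1b, a meiotic cohesin, was 50185-fold lower (95% counting interval 13892 to 414400) against 2 counts at spawning. Against groups with no count at spawning, rad21l1 was at least 13336-fold lower, sycp3 at least 8893-fold and piwil1, which acts in germ cells against transposons, at least 4882-fold. Of 82 spermiogenesis and flagellum genes 75 fell and 4 rose, with cfap61 at -8.03 ± 0.29 and dnai3 at -8.02 ± 0.26. With 4 up and 75 down adjusted over the list alone, the list had a preset adjusted p of 2.89e-21, and adjusted p = 0.307 with an estimated correlation. Of 26 cell proliferation genes 24 fell and 1 rose, with the mitotic kinases aurka and ttk at -9.54 ± 0.29 and -6.59 ± 0.22. With 1 up and 24 down adjusted over the list alone, the list had a preset adjusted p of 7.91e-20, and adjusted p = 0.0210 with an estimated correlation. The Leydig cell hormone insl3 rose by 11.34 ± 0.82, from 7.80 ± 4.19 to 20180 ± 7127 CPM, and star by 8.24 ± 0.68, from 13.3 ± 6.92 to 4025 ± 1569 CPM. The creatine transporter slc6a8 rose by 11.81 ± 0.67, crlf1a by 10.08 ± 0.93 and the complement gene c7b by 9.83 ± 0.62, and slc6a18 was at least 2305-fold higher than in ocean males.

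Of 12 Sertoli and Leydig cell genes 11 rose and 1 fell (11 up and 1 down adjusted over the list alone; preset adjusted p = 0.00120, adjusted p = 0.418 with an estimated correlation). Among them the receptors fshr and lhcgr changed by 5.07 ± 0.35 and 6.94 ± 0.54, and amh by 4.25 ± 0.40. All 10 endothelial genes rose, with vwf at 6.46 ± 0.41 and plvapb at 6.14 ± 0.34. With 10 up and 0 down adjusted over the list alone, the list had a preset adjusted p of 3.42e-04, and adjusted p = 0.418 with an estimated correlation. Of 22 collagen and matrix genes 19 rose and 1 fell, with fbn1 at 4.96 ± 0.30. With 19 up and 1 down adjusted over the list alone, the list had a preset adjusted p of 0.0120, and adjusted p = 0.540 with an estimated correlation. All 6 glucocorticoid response genes rose, with klf9 at 4.38 ± 0.27. With 6 up and 0 down adjusted over the list alone, the list had a preset adjusted p of 0.00764, and adjusted p = 0.307 with an estimated correlation. All 12 proteasome genes fell, psma2b among them (-2.39 ± 0.18). With 0 up and 12 down adjusted over the list alone, the list had a preset adjusted p of 0.00280, and adjusted p = 0.513 with an estimated correlation. Of 33 genes on the ribosomal protein list 29 fell and 4 rose, with a preset adjusted p of 0.0718 under library-size scaling; the kinases rps6ka1 and rps6kal were among the risers, and the kinase rps6ka5 and the kinase-like rps6kc1 among the fallers. With 4 up and 29 down adjusted over the list alone, the list had a preset adjusted p of 0.0351, and adjusted p = 0.589 with an estimated correlation. Of 10 steroidogenesis genes 7 rose and 1 fell (7 up and 1 down adjusted over the list alone; preset adjusted p = 0.0750, adjusted p = 0.513 with an estimated correlation). The gene hsd20b2, an enzyme linked to maturation-inducing steroid synthesis, was 422-fold lower (95% counting interval 144 to 2050) against 3 counts at spawning. The estrogen receptor esr1 rose by 5.46 ± 0.42 and the progesterone receptor pgr by 3.21 ± 0.37, while the gonadal growth factor igf3 fell by 1.94 ± 0.49. In all, 11462 genes rose and 12170 fell of 28149 tested.

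The testis was the tissue in which the ocean-to-river step called most genes, 7273 up and 3764 down. The cytokine-like factor gene crlf1a rose by 4.90 ± 0.94, from 0.0983 ± 0.0644 to 3.31 ± 3.94 CPM (n = 5), the phosphate transporter slc34a1a by 3.87 ± 0.64 and the Wnt receptor fzd8a by 3.83 ± 0.70. The genes slc5a6a, cbsa and spinb changed by -1.85 ± 0.31, -1.76 ± 0.56 and -1.49 ± 0.25 (adjusted p = 0.337 for cbsa with fish number as a replicate block). Somatic cell lists already moved in this step, and 9 of 10 endothelial genes rose (9 up and 0 down adjusted over the list alone; preset adjusted p = 0.00110, adjusted p = 0.660 with an estimated correlation). Sertoli and Leydig cell genes rose in 9 of 12 cases (9 up and 0 down adjusted over the list alone; preset adjusted p = 0.0103, adjusted p = 0.660 with an estimated correlation). Collagen and matrix genes rose in 13 of 22 cases (14 up and 0 down adjusted over the list alone; preset adjusted p = 0.00110, adjusted p = 0.660 with an estimated correlation). Of 82 spermiogenesis and flagellum genes 30 rose and 3 fell (32 up and 3 down adjusted over the list alone; preset adjusted p = 0.00210, adjusted p = 0.677 with an estimated correlation), and of 26 cell proliferation genes 11 fell and 2 rose. With 3 up and 12 down adjusted over the list alone, the list had a preset adjusted p of 0.0112, and adjusted p = 0.660 with an estimated correlation. The balance of rises and falls differed between settings: with library size only, 5084 genes rose and 6563 fell and the median of all genes went from 0.25 to -0.01, a fit of these 2 stages alone gave 5795 and 5522, and no filter gave 5530 and 5254. With fish number as a replicate block 2349 genes were called in total. From river to spawning 10923 genes rose and 11771 fell, with slc6a8 at 10.62 ± 0.63, apof 1747-fold higher (95% counting interval 313 to 69027) against 1 count in the river, slc6a18 at 10.00 ± 0.47 and sycp1 at -16.90 ± 0.78, and with rad21l1 and sycp3 at least 9912-fold and 9342-fold lower. In that step 27 of 28 germ cell genes fell (1 up and 27 down adjusted over the list alone; preset adjusted p = 3.50e-35, adjusted p = 0.0155 with an estimated correlation). Flagellum genes fell in 75 of 82 cases (3 up and 75 down adjusted over the list alone; preset adjusted p = 3.28e-25, adjusted p = 0.252 with an estimated correlation). Library-size scaling moved the median of all genes from -0.09 to 0.25.

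**Figure D4:**
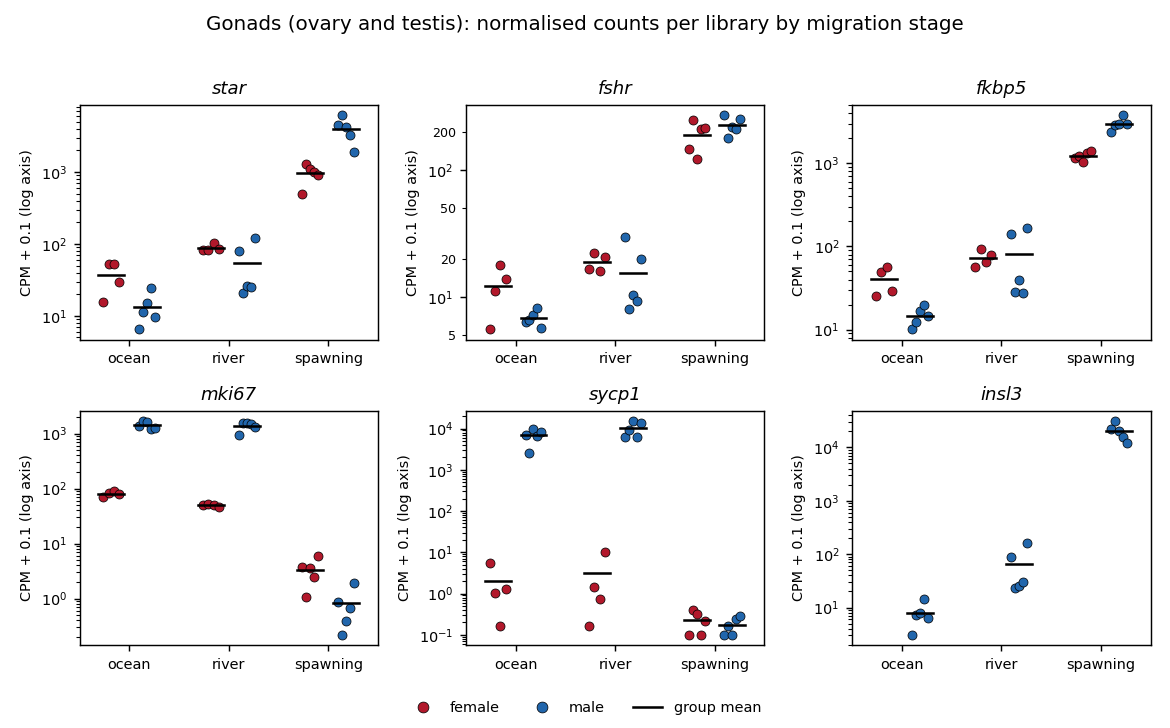
Levels of 6 genes in each gonad library (CPM + 0.1, log axis) at the 3 stages, ovary in red and testis in blue, with a black bar at each group mean; insl3 is shown for testis only. In testis sycp1 and mki67 drop at spawning while star and insl3 climb, and in ovary star and fkbp5 climb.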

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

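The tests of a mixture in the river male 6 muscle library, of pairs of libraries by tubule score, of the share of blood-forming cells and of the glycolysis pattern were chosen only after those results were seen. The fits with tissue scores were added after the stage results were seen; what they and the wrong label test would show was written down before their own results. The library labelled river male 6 muscle lay with the spawning muscle libraries, with gapdh at 3.86 CPM and pfkma at 1495 CPM. A mixture of river and spawning RNA is argued against by its gapdh level, 0.491% of the lowest of the other river males, whose own transcripts would remain in a mixture. A wrong label remains a candidate explanation: its on or off state equalled that of the testis library of river male 6 in 9 of 12 informative genes and that of its head kidney library in 11 of 13, but equalled the testis of spawning male 6 in 13 of 13 and the head kidney of spawning male 6 in 12 of 12, against 57.1% to 83.3% in the testes of other males. The labels list no muscle library of spawning male 6. An early change in 1 river male would need muscle of that fish, which the on or off states argue against. Its other tissues do not decide this. In head kidney of river male 6 fkbp5 was at 477 CPM (other river males 21.7 to 152, spawning males 238 to 433) and klf9 at 15.01 (2.51 to 4.90, spawning 38.3 to 55.1). In its testis fkbp5 was at 167 CPM (27.6 to 140, spawning 2416 to 3780) and sycp1 at 14050 (6365 to 15090).

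Lymphocyte genes were lower at spawning in the head kidney of both sexes, with list medians of -1.95 in females and -2.15 in males; with an estimated correlation the call of the list holds in females (adjusted p = 0.0229) and is lost in males (0.101). Dilution by renal tubule would need more tubule tissue at spawning, whereas the mean tubule score went from 5.42 to 1.90 in females and from 1.91 to -0.284 in males. It is argued against because in all 16 and 12 pairs with no higher tubule score at spawning the lymphocyte score was lower there, the highest differences being -1.26 in females and -0.974 in males. The medians with the tubule score alone in the model (-1.93 and -2.39) test nothing, as that score did not go up. Dilution by tubule and interrenal tissue together is argued against because the medians were -1.92 and -2.40 with both scores. A lower share of all blood-forming cells is argued against in females, where the proliferation and erythroid lists had medians of -0.0848 and -0.0727, although flt3, a receptor of blood cell precursors, changed by -1.59. In males it stays open: the proliferation median was -0.0458, but the erythroid median was -1.26 with 5 of 10 genes down, flt3 changed by -1.86, and the complement and macrophage list went up (median 0.497), so it cannot be told apart from a change in lymphocytes alone. In females a fall in lymphocytes or in their transcription over the migration remains as a hypothesis, found and tested on the same data. Which of the 2 it could be, and the part of stage-linked factors such as water and feeding, were not tested.

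In muscle 10 of 14 glycolysis genes fell and 2 rose from ocean to spawning in females, and 7 of 14 fell and 2 rose in males, calls of the list that are lost with an estimated correlation (adjusted p = 0.4935 and 0.740). The tests below take the 7 members with a mean of at least 100 CPM in ocean or spawning, pfkma among them; their medians were -7.15 and -9.91, with errors of 3.41 and 3.67. Scaling by a few abundant genes is argued against for these 7, since their highest median over 3 scalings was -6.22 in females and -8.76 in males. It is not argued against for the list as a whole, whose median over all 14 was -2.25 and -1.99, and -1.58 and -0.738 with library size only, with errors of 1.94 to 2.19. Reads moving to 1 other gene copy are argued against for gapdh, eno3 and ldha, since the largest gain in mean CPM of any gene was 20.1%, 38.3% and 47.6% of their losses in females and 19.7%, 36.2% and 41.7% in males (standard errors 4.46 to 12.5). For pygma, pfkmb and eno1a it cannot be told apart from a real fall: the same gain was 96.8% to 1039.5% of their losses in females and 116% to 961% in males, all from 1 gene with no symbol, which cannot be the copy of all 3. The named copy pfkma gained 15.98% and 15.9% of the loss of pfkmb, and the named copy eno1b -1.57% and 0.0633% of the loss of eno1a. These 2 groups of genes were formed after their percentages were seen. Other muscle in place of fast muscle was not tested. A tissue without sarcomeres would lower sarcomere genes as much. In females the 5 at that level had a median of -1.54, which argues against it. In males it stays open for part of the fall, as the median of 4 was -3.38. Both outcomes depend on the choice of genes, made on 3 sets in turn, each after the values of the one before were seen, and a 4th set of all tested members. The called fallen glycolysis members (medians -5.53 and -9.91) against 4 sarcomere genes chosen by ocean level (-2.32 and -3.38) left it open in both sexes. With both lists chosen by ocean level (-9.31 and -10.82 against the same 4) it was argued against in both, and with all tested members (-2.25 and -1.99 against 0.308 and 0.193) in females only. The smallest number of sarcomere genes was raised from 3 to 5 after the 2nd set was seen, and is 3 again here; with 5, the 2nd set leaves it open in both sexes. A change within muscle over the migration also stays open.

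Some single libraries stood far from the others of their group, in 7 of 65 groups of key gene values checked, where chance gives about 1 in 20. In spawning female gonads 1 pgr was 194 CPM, against 62.95 to 89.2 in the other libraries. In ocean male gonads 6 piwil1 was 151 CPM, against 187 to 199. In river female head kidney 7 rag1 was 2.60 CPM, against 6.39 to 6.55. The gene star was at 3321 CPM in river female head kidney 8 (others 0.142 to 292), 2029 in ocean male 9 (0.0955 to 0.430), 187 in river male 5 (0 to 1.24) and 895 in spawning male 10 (0.803 to 7.14). The change from ocean to spawning in muscle differed between the sexes for b3galt1b by 6.42 (female minus male, log2, edgeR adjusted p = 0.0161), abraa by 3.11 (adjusted p = 0.0322) and rasgrp3 by 2.79 (adjusted p = 0.0322). The calls were also lost for b3galt1b with limma-voom (0.120), for abraa with library-size scaling (0.0607) and for rasgrp3 with library-size scaling (0.0661) and limma-voom (0.0858). They were lost without some single libraries: b3galt1b without ocean female 2 or 4, ocean male 3 or spawning male 7 or 8 (adjusted p 0.0513 to 0.0891), abraa without any ocean female, ocean male 1 or 3, spawning female 2 or 5 or spawning male 8 (0.0509 to 0.0958), and rasgrp3 without ocean female 2, 4 or 5, ocean male 3, spawning female 2 or 5 or spawning male 7 or 8 (0.0509 to 0.114).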

How the results depend on the processing

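The alternatives described at the start as added were chosen only after the results were seen, and the others were set before. Of 361 counts under an alternative 240 stayed within 1.5 times the reported one, 86 were lower and 35 higher; of 1135 list tests 977 and of 7578 tests of named genes 6869 kept direction and side of the threshold, and the cause of the departures below was not tested unless stated. DESeq2 called 372 (head kidney) and 620 (muscle) sex differences, 96 and 295 interactions, 149 genes in ovary, 1536 and 170 in female and male head kidney and about 3.5e+02 and 747 in female and male muscle from ocean to river, 4339 and 3671 in female and male head kidney from ocean to spawning, and 3943 and 4743 from river to spawning. Fits of 2 stages called 107 and 15 genes in female and male muscle from ocean to river, and 907 in female head kidney and 3061 in male muscle from river to spawning. Library size only called 512 and 6324 in female and male muscle from ocean to river, 3398 in male muscle from river to spawning and 5 muscle interactions, and put tp53inp1 in male muscle at 0.39 (adjusted p = 0.269), the opposite direction. Without a filter 4 genes in female head kidney and 14 in female muscle were called from ocean to river. With limma-voom 0 and 45 sex differences were called in head kidney and muscle, and 5 muscle interactions. With the tubule score 1283 genes in female head kidney were called from ocean to river and 4088 from river to spawning, and with both scores 5 from ocean to river and 3901 from ocean to spawning. The renal tubule list in female head kidney changed direction with the tubule score (adjusted p = 0.0411) and with both scores (0.0289), as the score holds its own members, and the epithelium and skin list with both (0.0446). With fish number as a replicate block, although the numbers pair nothing (r of the 18 shared numbers -0.528 to 0.359), 2349 genes were called from ocean to river in testis, and from ocean to spawning 5528 in ovary, 5422 in female muscle and 59 and 0 in female and male head kidney; there the epithelium and skin list (adjusted p = 0.0255) and the renal tubule list (0.0210) changed direction in males. Leaving out 1 library gave from ocean to spawning 9754 to 11532 in female muscle, 5464 to 9131 in male muscle, 887 to 2113 in female head kidney, 942 to 3462 in male head kidney, 8452 to 10968 in ovary, 23528 to 23757 in testis, from ocean to river 0 to 45 in female muscle, 0 to 219 in male muscle, 0 to 83 in female head kidney, 0 to 1 in male head kidney, 0 to 0 in ovary, 8076 to 11674 in testis, and from river to spawning 9333 to 11129 in female muscle, 1444 to 11077 in male muscle, 1341 to 2125 in female head kidney, 1113 to 2458 in male head kidney, 8646 to 11293 in ovary, 22423 to 22997 in testis. The same gave 6 to 48 and 53 to 398 sex differences in head kidney and muscle and 0 to 0 and 1 to 143 interactions. Without river male 6, which shared filter, scaling and spread, 10948 genes were called from ocean to spawning in male muscle. Of 478 called named genes 168 lost the call or changed direction under at least 1 alternative. With 3 to 5 libraries per group and these depths few 2-fold changes are recovered (0% to 39% in simulated data), so a gene that was not called may have changed.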

Other observations

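The search for genes that moved alike in all tissues, and the genes named from it, were chosen only after the results were seen; the count of other splits was set before. Of 19345 genes tested in all 6 combinations of tissue and sex, 90 rose and 12 fell from ocean to spawning in all 6, where independent calls would give 0.234 and 0.0263; the tissues come largely from the same fish, so the calls are not independent. Of these, 13 risers and 4 fallers carry a symbol. Without each ocean or spawning library in turn and with library size only (56 fits over the 6 combinations), 3 of these 17 kept every call, the cortisol-responsive transcription factor klf9 (1.89 to 5.76 on the log2 scale), the MAP kinase phosphatase dusp6 (1.36 to 5.22) and tspan36 (1.46 to 7.58). None of the 3 keeps its call in male head kidney with fish number as a replicate block, which calls 0 genes there; the adjusted p of klf9 was 0.0543 and 0.135 in female and male head kidney. The other 14 lost a call in 2 to 17 of the fits. Among them the CDK inhibitor cdkn1ba (0.79 to 5.27) was not called in female head kidney without any 1 of ocean females 2, 4, 5 and 7 and spawning females 1, 4 and 5 (adjusted p 0.0544 to 0.104) or with library size only (0.0762). The receptor of blood cell precursors flt3 (-1.59 to -4.36) was not called there without any 1 of ocean females 2, 4, 5 and 7 and spawning females 1 and 5 (0.0589 to 0.0863).

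Other splits of the same libraries into groups of the same sizes were fitted to see whether chance could give as many calls. With 35 splits the real one can be at best 1 of 35, and the shares were not adjusted over the comparisons. Chance can therefore be argued against but not excluded. From ocean to spawning it is argued against in each tissue and sex, since 1 split, the real one, reached its count in each: 1 of 35 in female muscle (10950 genes, highest other 4), male muscle (8866, 159), female head kidney (2167, 1) and male head kidney (1819, 0), and 1 of 100 in ovary (10286, 4092) and testis (23632, 1). From ocean to river it is argued against, again with 1 split, in female muscle (1 of 35, 9 genes, highest other 2), male muscle (1 of 100, 32 and 1), female head kidney (1 of 35, 32 and 1) and testis (1 of 100, 11037 and 3308). The counts of this step in muscle and female head kidney fell to 0 without some single libraries. In male head kidney and ovary the real count was 0, which each of the 35 of 35 splits reaches whatever its count (highest other 7670 and 1), so the splits say nothing of chance there. From river to spawning it is excluded in female muscle (1 of 35, 10487 genes, highest other 1), male head kidney (1 of 35, 2479 and 1), ovary (1 of 100, 10734 and 3589) and testis (1 of 100, 22694 and 994), and in male muscle, where 2 of 56 splits reached the real count (5127, highest other 9338). It is not excluded in female head kidney, where 2 of 35 did (2315, highest other 6208). For the sexes chance is argued against for the muscle interaction (1 of 60, 12 genes, highest other 6) and the muscle sex difference (1 of 60, 149 and 7). It is not for the head kidney sex difference (3 of 60, 15 and 1185). The head kidney interaction had a real count of 0, which 60 of 60 splits reach (highest other 2), so the splits say nothing there.

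Splits with more calls than the real one point to a structure of the samples. In male muscle the split with 9338 genes grouped river 6 with spawning 8 and 9. In female head kidney the split with 6208 genes grouped river 8 and 9 with spawning 4 and 5, whose steroidogenesis scores were 3.85 to 5.34 against 1.3985 to 2.89 in the others (tubule scores -1.49 to -1.08 against -1.60 to 5.07). In male head kidney from ocean to river the split with 1609 genes put together ocean 6 and 9 and river 3 and 5, with tubule scores of -1.43 to -0.826 against 4.24 to 5.93. Another with 7670 genes put together ocean 8 and river 2, 3 and 6, which neither score parts from the others (tubule -1.39 to 5.93 against -1.43 to 5.66, steroidogenesis 1.38 to 1.98 against 1.34 to 5.93). Nor does either score part the groups of the split with 1185 genes for the head kidney sex difference (tubule -1.43 to 5.93 against -1.60 to 5.83, steroidogenesis 1.32 to 5.93 against 1.00 to 5.34), or those of another there with 761 genes (tubule -1.49 to 5.93 against -1.60 to 5.83, steroidogenesis 1.30 to 5.93 against 1.00 to 5.34).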
